A study of Mus musculus with 9 samples.

How the data were processed

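Cells were sorted from the main olfactory epithelium of mice aged 4 weeks, and poly-A RNA was sequenced from 1 library of each of 3 populations, per the labels' protocols. The HBC library was prepared with ScriptSeq and the GBC and mOSN libraries with the Illumina mRNA kit, per the labels' protocols. Samples were grouped by their titles. The series also lists 3 samples of 5-hydroxymethylcytosine and 3 of 5-methylcytosine, which were not analysed here.

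The authors deposited 1 table per library with FPKM (fragments scaled to transcript length and to mapped fragments) per gene, the lower and upper bound of its interval and a status, per the file headers. The submitters' processing notes name Bowtie, TopHat and Cufflinks and the mouse build mm9, without versions. The annotation and the Cufflinks options are not given in the sources used here. Each table had 22345 rows for 21909 gene symbols. Rows of 1 symbol were added up, which concerned 222 symbols with 658 rows. Status FAIL was carried by 8 rows in HBC, 19 in GBC and 30 in mOSN, and LOWDATA by 247 rows in each. Such rows kept their deposited FPKM, but the interval of a FAIL row is widened and says little. Starts were raised by 1 so that coordinates count from 1 as in a genome browser. Gene symbols are those of the files, and a gene table with synonyms served only to match 10 list symbols through synonyms, with 568 of 571 list symbols matched.

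Depth was read from the deposited intervals. A half-width of 2 times the FPKM divided by the square root of a count n gives an implied n for each row. Among rows with at most 100 implied fragments, 77.7% in HBC, 69.5% in GBC and 68.8% in mOSN came out within 0.03 of a whole number, where chance gives 6%. The totals were 18123443 in HBC, 18087564 in GBC and 16516700 in mOSN. Intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The implied fragments behind 1 FPKM of the same gene differed between libraries. Among 10152 genes with at least 50 fragments in GBC and HBC, the ratio of that conversion spanned 8.16-fold from the 5th to the 95th percentile, and 2.26-fold between mOSN and GBC. How the authors' software set that conversion was not tested, and its effect is given by the alternative with 1 conversion factor per gene.

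Ratios were log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes. A gene was called higher in a library at a log2 ratio of at least 2 (a 4-fold difference) and at least 5 FPKM there. With 1 library per group there was no test between groups and no p-value. The design called for no count test, and none was run. In total 35 gene lists were written before the data were examined, 29 by symbol and 6 by a pattern of symbols. They covered stages of the olfactory lineage, receptor families, signal transduction, cilia, synapse, axon guidance, cell cycle, chromatin, DNA methylation, metabolism, dissociation response and the other cell types a sort of this tissue can hold. A member counted as measured at 1 FPKM in either library. Where more members of a list reached that level in 1 library, the filter favoured that library. The median log2 ratio of each list with at least 3 measured members was given as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Percentiles under 2.5 or over 97.5 are described as outside the random range. They describe these libraries and are no test of the populations. Members at least 2-fold different were counted as higher or lower.

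Genes were named by a rule set before the data were examined. It took Omp, Neurog1 and Icam1, the 8 largest ratios per direction among genes of at least 20 FPKM (without receptor, predicted and immune receptor segment symbols), up to 4 members per list with the largest absolute ratio at 5 FPKM or more, 7 Tet, Dnmt and Uhrf1 genes, and the 5 receptor genes with the highest FPKM in mOSN. Some genes of that rule are not reported here. Among the genes of that rule with at least a 2-fold difference and 1 interval per library, the 2 intervals overlapped for 1 of 97 between mOSN and GBC (Dnmt1), and for 0 of 123 between GBC and HBC and 0 of 126 between mOSN and HBC.

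The alternatives set before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter on low values, a filter at 20 FPKM, rescaling to a common sum (TPM scale), median-of-ratios scaling, the highest row per symbol, intervals that do not overlap, and leaving out predicted genes. After seeing the data, 2 more were added, 1 conversion factor per gene and leaving out FAIL and LOWDATA rows. A further one, limited to genes with a long implied effective length, was run after seeing the data and dropped, because that measure turned out not to be a transcript length.

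The rule and the list percentiles were tested on simulated data of 21909 genes per comparison. Of 200 genes changed 8-fold, 200 were recovered in each comparison, with 4 false calls for mOSN against GBC, 0 for GBC against HBC and 0 for mOSN against HBC. Of 200 unchanged lists, 11, 7 and 7 fell outside the random range in those comparisons, and 20 of 20 shifted lists lay above it. Both simulated libraries came from 1 deposited library with counting error only, so differences in kit, conversion and biology were absent. An 8-fold change also lies well above the 4-fold rule. These counts therefore check the rule as written and not its error rate in the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.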

Results

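Messenger RNA was measured in 3 cell populations sorted from the main olfactory epithelium of 4-week-old mice. The olfactory epithelium renews its sensory neurons throughout life. Horizontal basal cells (HBC) are a reserve stem cell layer and were sorted by an antibody to CD54, the protein encoded by Icam1. Globose basal cells and early neuronal precursors (GBC) were sorted by an enhanced green fluorescent protein (EGFP) reporter of Neurog1. Mature olfactory sensory neurons (mOSN) were sorted by an EGFP reporter of Omp, the olfactory marker protein gene. Each population was represented by 1 library, so no difference below has a replicate check and no p-value is given. The HBC library was made with the ScriptSeq kit and the other 2 with the Illumina mRNA kit, so kit and cell population are confounded in every comparison with HBC. The series also holds 3 samples of 5-hydroxymethylcytosine and 3 of 5-methylcytosine from the same populations, which were not analysed here.

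The values were FPKM for 21909 gene symbols. The fragments implied by the deposited intervals summed to 18123443 in HBC, 18087564 in GBC and 16516700 in mOSN. At least 1 FPKM was reached by 11388 genes in HBC, 11395 in GBC and 11547 in mOSN. The gene with the highest FPKM was Apoe in HBC (5045 FPKM), Tuba1a in GBC (1871 FPKM) and S100a5 in mOSN (2918 FPKM). Across genes, the Spearman correlation was 0.911 between mOSN and GBC, 0.690 between GBC and HBC and 0.664 between mOSN and HBC. Genes are not independent replicates, so these values describe the libraries only.

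The genes behind the sorts were compared first. Icam1 (chromosome 9, 20820404 to 20833240, mm9) had 136 FPKM in HBC (Cufflinks interval 134 to 139), 0.046 in GBC and 0.35 in mOSN. Neurog1 (chromosome 13, 56351860 to 56353524), a proneural transcription factor, had 163 FPKM in GBC (interval 160.3 to 165), 0.054 in HBC and 0.019 in mOSN. The HBC and mOSN values of Neurog1 rested on 2 and 1 implied fragments. Omp (chromosome 7, 105291869 to 105293957) had 1487 FPKM in mOSN (interval 1477 to 1497), 427 in GBC (interval 423 to 432) and 71.6 in HBC (interval 69.4 to 73.9). Each sort gene was therefore highest in the library named for it, and Omp was also present in the other 2 libraries.

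**Figure D1:**
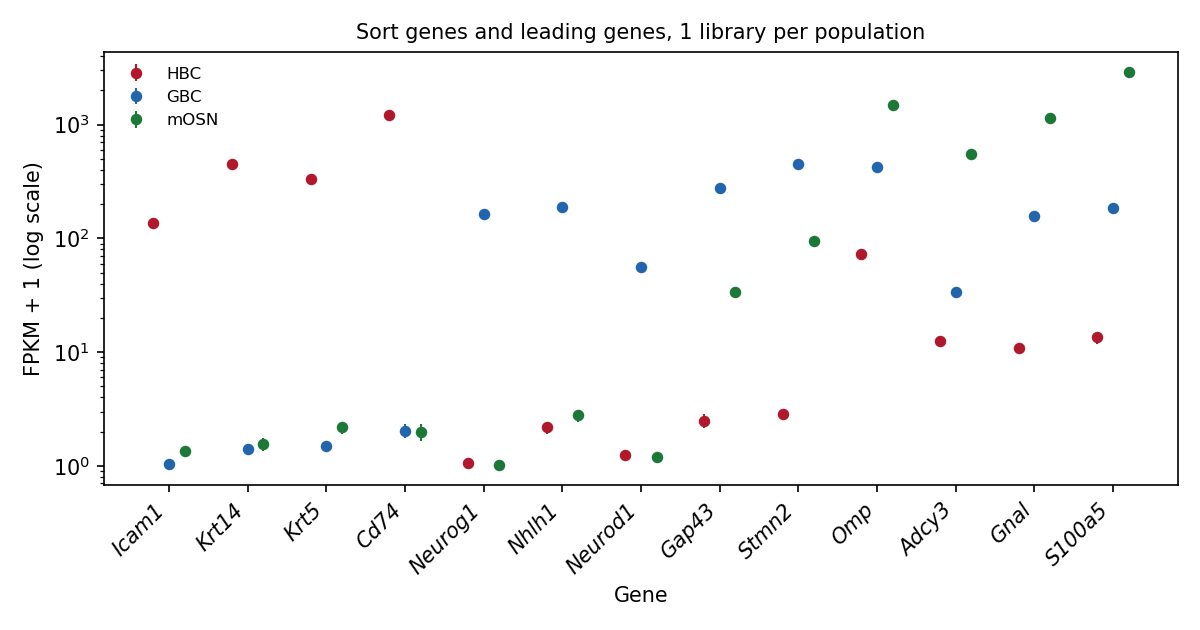
FPKM + 1 on a log axis for 13 genes in the HBC, GBC and mOSN libraries, where each point is 1 library and each bar the deposited Cufflinks interval. Icam1, Krt14, Krt5 and Cd74 were highest in HBC, Neurog1, Nhlh1, Neurod1, Gap43 and Stmn2 in GBC, and Omp, Adcy3, Gnal and S100a5 in mOSN.

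The mOSN and GBC libraries, made with the same kit, addressed the step from neuronal precursor to mature neuron. Genes of odorant signalling were higher in mOSN. Of 20 measured genes of olfactory signal transduction, 15 were at least 2-fold higher in mOSN and 2 lower, with a median log2 ratio of 2.29. Adcy3, the adenylyl cyclase of the odorant cascade, had 547 FPKM in mOSN and 32.8 in GBC. The cyclic nucleotide-gated channel subunits Cngb1 (114 against 6.72 FPKM) and Cnga4 (264 against 19.4 FPKM) and the exchanger Slc24a4 (57.9 against 3.52 FPKM) were also higher. Of 22 mature neuron markers, 17 were at least 2-fold higher and none at least 2-fold lower (median 2.19), among them S100a5 (2918 against 185 FPKM), Stoml3 (2148 against 158 FPKM) and Umodl1 (528 against 28.2 FPKM). These lists overlap, since 10 of the 22 mature neuron markers stand in another list, and both medians lay above all 10000 random lists matched on mean expression.

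Precursor genes were higher in GBC. Of 15 measured globose basal cell and precursor markers, 11 were at least 2-fold lower in mOSN (median log2 ratio -3.21). Nhlh1, a neuronal helix-loop-helix factor, had 188 FPKM in GBC and 1.78 in mOSN. Neurod1 had 55.0 and 0.193 FPKM, and Cxcr4, a chemokine receptor, 59.6 and 0.454 FPKM. Immature neuron markers were lower in mOSN in 14 of 20 (median -2.24), with Gng8 at 129 against 2.001 FPKM, Dpysl3 at 419 against 10.5 FPKM and Tubb2b at 524 against 26.8 FPKM. Of 28 measured cell cycle genes, 20 were at least 2-fold lower in mOSN and none higher (median -1.45). Top2a, a replication topoisomerase, had 9.57 FPKM in GBC and 0.403 in mOSN, and the proliferation marker Mki67 had 6.54 and 0.240 FPKM. Histone genes were lower in mOSN in 40 of 56 and higher in 2 (median -1.29), though their summed FPKM was 845 in mOSN and 831 in GBC. At 1 FPKM there were 56 histone genes in GBC and 32 in mOSN, and 28 and 8 cell cycle genes. The filter on measured members therefore favoured GBC in both lists. Ribosomal protein genes were lower in 38 of 84 and higher in 1 (median -0.86), with Rps26 at 237 FPKM in GBC and 57.3 in mOSN. The ribosomal list was set by symbol and also holds ribosomal kinases such as Rps6ka1. Lineage transcription factors had a median of -0.96, with Dlx5 (21.3 against 1.01 FPKM) lower in mOSN.

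Genes of the cilium, which carries the odorant receptors, were higher in mOSN in 15 of 30 and lower in none (median 0.98). Bbs5, a Bardet-Biedl gene, had 21.1 FPKM in mOSN and 3.72 in GBC, and Dync2h1, the motor of retrograde ciliary transport, had 30.8 and 9.58 FPKM. Markers of motile multiciliated cells had a median of 1.12 (7 of 12 higher), with Ccdc40 at 46.9 against 12.2 FPKM, while Tekt2 went the other way at 1.22 against 19.0 FPKM. Axon guidance genes had a median of 0.77, with 14 of 31 higher and 5 lower. Plxna4 had 52.6 FPKM in mOSN and 9.99 in GBC, and Ephb2 had 0.203 and 8.13 FPKM. Synaptic vesicle genes had a median of 0.79 (9 of 23 higher), with Slc17a6, the vesicular glutamate transporter, at 101 against 13.1 FPKM and Syt1 at 107 against 19.5 FPKM. That list's median was 0.29, inside the random range, when each gene was given 1 conversion factor from fragments to FPKM in all libraries. Sustentacular cell markers, from the supporting cells of the epithelium, were also higher in mOSN (9 of 19, median 0.92), with the glucuronosyltransferase Ugt2a1 at 31.4 against 3.63 FPKM and Cyp2g1 at 46.1 against 7.76 FPKM.

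By the fixed rule, 618 genes were higher in mOSN and 274 in GBC, of 8678 genes reaching 5 FPKM in either. Slc1a2, a glutamate transporter, had 50.1 FPKM in mOSN and 1.36 in GBC, and the potassium channel gene Kcns3 had 35.6 and 0.938 FPKM. Phospho1 (46.0 against 1.53 FPKM), Clip4 (21.3 against 0.348 FPKM), Rnf128 (121 against 6.46 FPKM) and Dcdc2a (195 against 11.4 FPKM) completed the 8 largest ratios with Umodl1 and Adcy3. In the other direction, the retinoic acid-binding protein gene Crabp1 had 298 FPKM in GBC and 1.72 in mOSN, and Eya2 had 49.9 and 0.445 FPKM. The median gene was higher in mOSN by 0.29 on the log2 scale, and list medians are to be read against that shift. The share of called genes higher in mOSN was 69.3% as deposited, 60.2% with median-of-ratios scaling, 55.5% with 1 conversion factor per gene and 45.7% with each library rescaled to a common sum, which also lowered the weight of the pseudocount and the floor. With 1 conversion factor per gene, 17 of the 116 genes in the rule for this comparison moved by over 1.5-fold. Erythroid markers (median -1.43) were lower in mOSN, with Beta-s, a beta globin, at 68.1 against 260 FPKM, while the near-identical copies Hba-a1 and Hba-a2 went in opposite directions and are uncertain. Housekeeping genes had a median of -0.26, a percentile of 1.11 that was 7.95 with 1 conversion factor per gene. Medians inside the random range were 0.46 for the respiratory chain, 0.69 for immediate early genes, 0.54 for horizontal basal cell markers and 1.17 for microvillous and tuft cell markers. They were -0.02 for Polycomb and heterochromatin regulators, -0.09 for DNA methylation genes, -0.13 for interferon and MHC class I genes, -0.22 for macrophage markers and -0.36 for the Notch pathway. The rest of that kind were Bowman gland markers (-0.49), fibroblast and smooth muscle markers (-0.49), neutrophil markers (-0.51) and hemidesmosome genes (-0.55). Endothelial, lymphocyte, ensheathing glia, vomeronasal receptor and sort marker lists had too few measured members for a value.

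**Figure D2:**
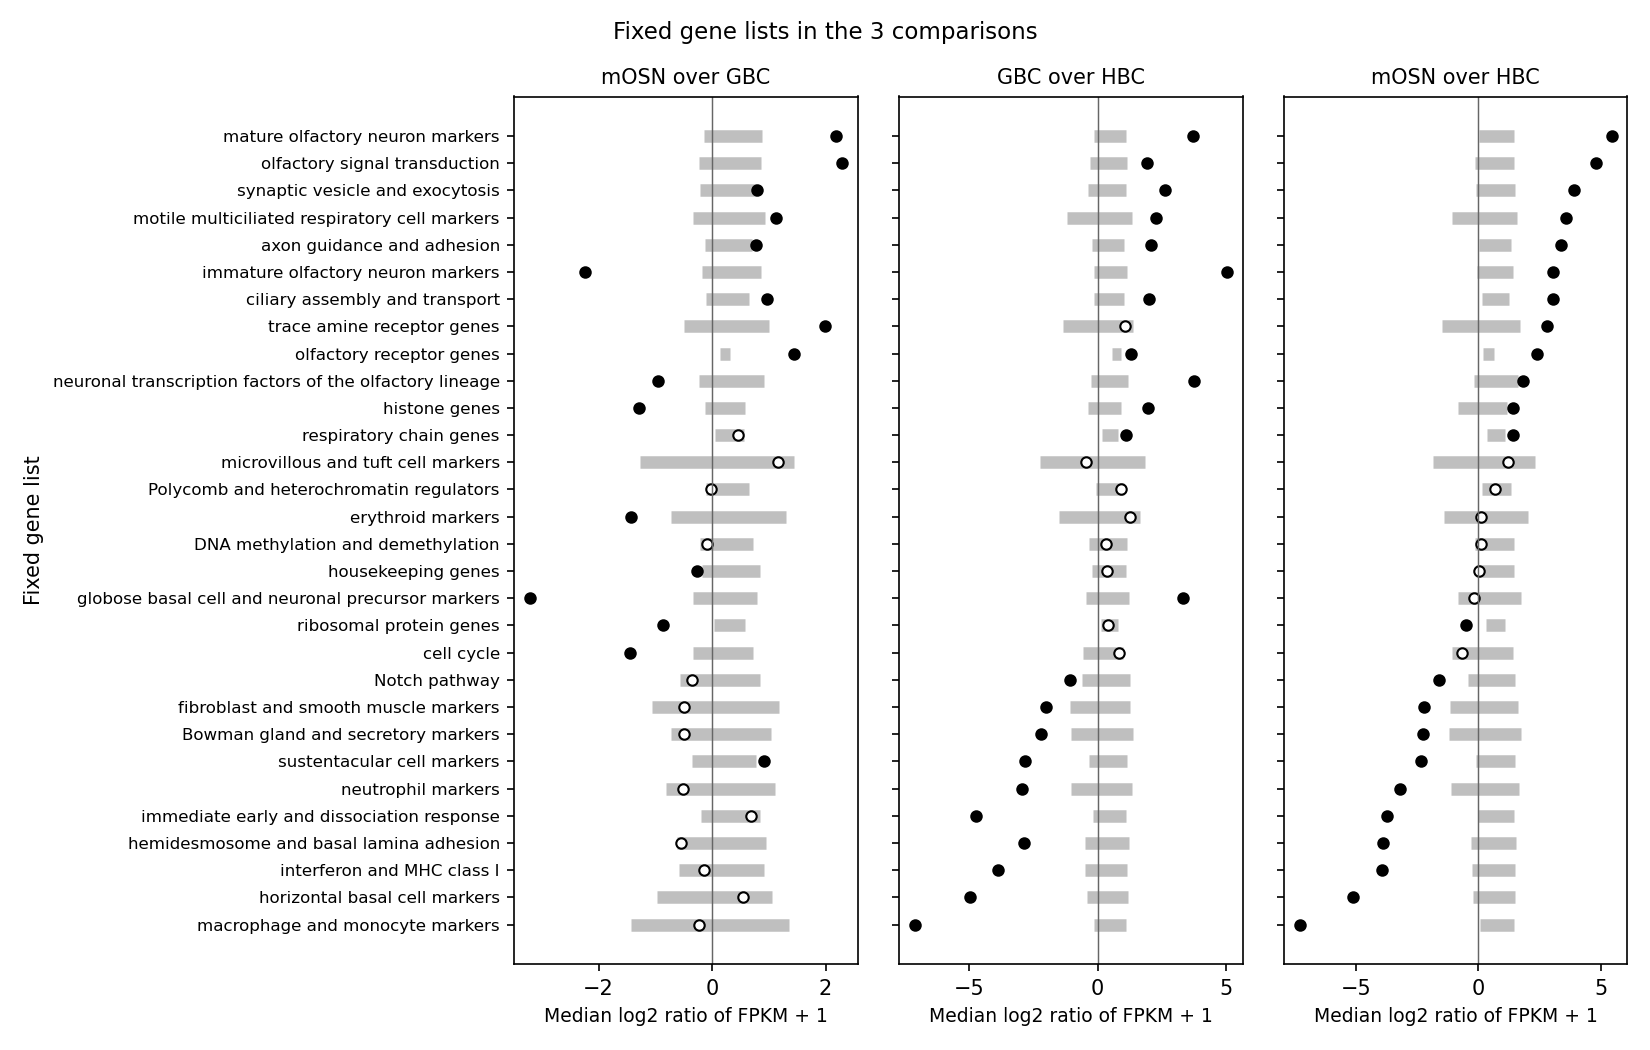
Median log2 ratio of FPKM + 1 for each fixed gene list with a value in all 3 comparisons, with the central 95% of random lists matched on mean expression in grey. Filled points lie outside that range and open points inside, and mature neuron markers had medians of 2.19, 3.70 and 5.45.

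Olfactory receptor genes, of which each sensory neuron is known to express 1 allele, were followed across the 3 libraries. Of 1112 receptor genes, 930 reached 1 FPKM in mOSN, 436 in GBC and 1 in HBC. Their summed FPKM was 5756 in mOSN, 1267 in GBC and 68.7 in HBC. At 5 FPKM the counts were 414, 21 and 0, and at 0.1 FPKM they were 1065, 1052 and 232. The highest in mOSN was Olfr536 (chromosome 7, 147686752 to 147693217), with 61.1 FPKM in mOSN, 22.8 in GBC and 0.580 in HBC. Olfr969 had 47.3 FPKM in mOSN and 2.40 in GBC, Olfr1348 had 47.2 and 10.3, Olfr1507 had 45.7 and 5.24, and Olfr533 had 40.1 and 12.3. Between mOSN and GBC, 700 of 954 measured receptor genes were at least 2-fold higher in mOSN and 18 lower (median 1.44). Trace amine receptors were higher in mOSN in 12 of 12 measured (median 1.99), with Taar9 at 8.75 against 0.511 FPKM. Of 15 such genes, 12 reached 1 FPKM in mOSN and 3 in GBC. The filter on measured members therefore favoured mOSN in both receptor families. Receptor genes are a family with similar members, and how fragments shared between them were counted is not given in the sources used here. In HBC 691 receptor genes were listed at 0, and a value of 0 there is not a measure of absence.

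**Figure D3:**
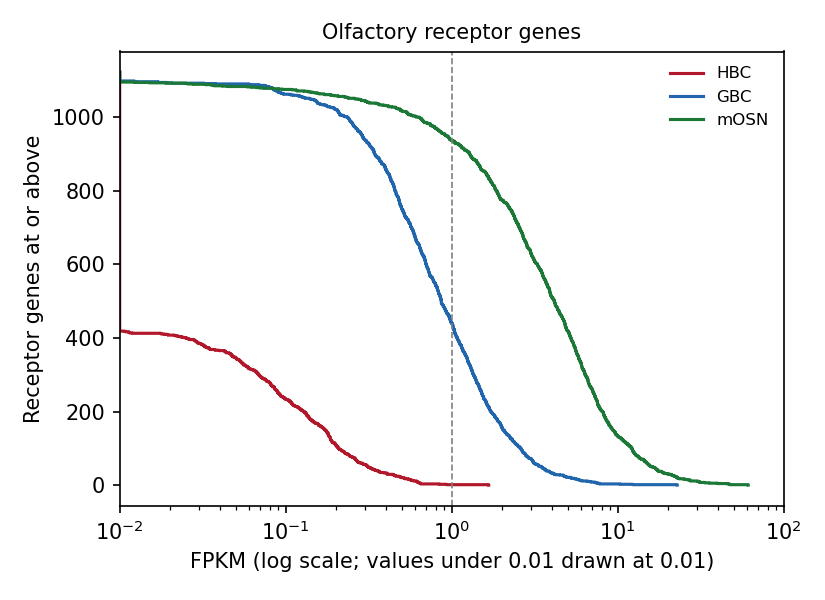
Number of olfactory receptor genes at or above each FPKM in the HBC, GBC and mOSN libraries, on a log axis with a dashed line at 1 FPKM. At that line 930 genes were counted in mOSN, 436 in GBC and 1 in HBC.

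The enzymes that write and oxidise DNA methylation were compared because the series concerns 5-hydroxymethylcytosine during differentiation. Tet3, a methylcytosine dioxygenase, had 11.7 FPKM in HBC (Cufflinks interval 11.4 to 12.1), 19.9 in GBC (interval 19.4 to 20.3) and 20.3 in mOSN (interval 19.7 to 20.8). Tet1 had 0.248 FPKM in HBC, 3.801 in GBC and 3.31 in mOSN, and Tet2 had 8.57, 2.81 and 3.36 FPKM. Macrophage markers were high in the same HBC library (list median 194 FPKM), so its values here may not be those of basal cells alone. Between GBC and mOSN the 3 Tet genes differed by log2 ratios of -0.15 (Tet1), 0.19 (Tet2) and 0.03 (Tet3), and Tet3 stood at -0.50 with 1 conversion factor per gene. Between HBC and mOSN the log2 ratio of Tet3 was 0.74 as deposited and -0.02 with median-of-ratios scaling. The de novo methyltransferase gene Dnmt3a had 8.78 FPKM in HBC, 34.0 in GBC and 46.0 in mOSN (interval 45.1 to 46.9). Dnmt3b was under 1 FPKM in all 3 libraries. The maintenance methyltransferase gene Dnmt1 had 11.4 FPKM in HBC and 6.97 in mOSN, and its value of 16.5 in GBC came from a row with the status FAIL and an interval of 0 to 26.1. Uhrf1, its partner at replicated DNA, had 2.48 FPKM in HBC, 1.61 in GBC and 0.256 in mOSN. The list of DNA methylation and demethylation genes as a whole lay inside the random range in all 3 comparisons. Limited to members of at least 20 FPKM, its median was below that range in GBC against HBC (-0.78) and in mOSN against HBC (-1.005), and in the latter also with libraries rescaled to a common sum (-0.76). Within it, Gadd45g had 58.6 FPKM in HBC, 10.5 in GBC and 0.912 in mOSN, and Cxxc5 had 10.2 FPKM in GBC and 0.669 in mOSN.

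**Figure D4:**
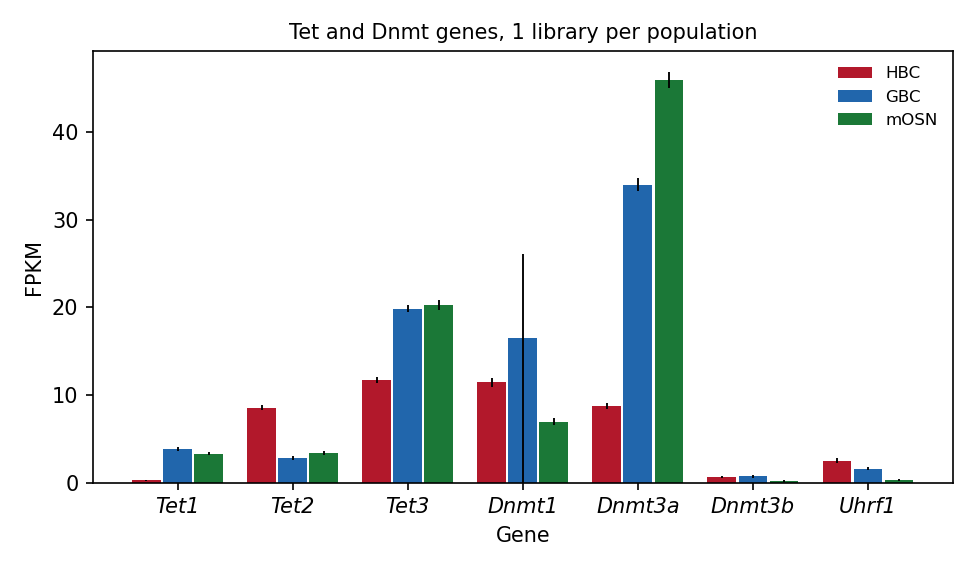
FPKM of 7 genes of DNA methylation and its oxidation in the HBC, GBC and mOSN libraries, with the deposited Cufflinks interval as the error bar. Dnmt3a stood at 8.78, 34.0 and 46.0 FPKM, and the wide bar of Dnmt1 in GBC belongs to a row with the status FAIL.

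The GBC and HBC libraries addressed the step from the reserve stem cell layer to neuronal precursors. Neuronal genes were higher in GBC. Of 20 immature neuron markers, 17 were at least 2-fold higher and 1 lower (median log2 ratio 5.04), with Stmn2, a tubulin-binding protein of growing neurites, at 448 FPKM in GBC and 1.84 in HBC, and Gap43, a growth cone protein, at 277 and 1.497 FPKM. Lineage transcription factors had a median of 3.75 (14 of 18 higher), with Lhx2 at 170 against 2.497 FPKM, Ebf2 at 173 against 2.34 FPKM and Atf5 at 1130 against 23.7 FPKM. Precursor markers had a median of 3.32 (10 of 16 higher, 4 lower), with Nhlh1 at 188 against 1.18 FPKM. Mature neuron markers were higher in GBC in 22 of 22 (median 3.70), with Calb2 at 259 against 2.64 FPKM, and signal transduction genes in 14 of 20 (median 1.94), with Gng13 at 133 against 5.25 FPKM. Synaptic vesicle genes (median 2.61), axon guidance genes (median 2.09), ciliary genes (median 1.98) and motile multiciliated cell markers (median 2.29) were higher as groups. Examples were Stx1a at 60.8 against 1.17 FPKM, Ncam1 at 143 against 3.81 FPKM, Kif3a at 32.6 against 2.06 FPKM and Tekt1 at 13.3 against 0.374 FPKM. Histone genes were higher in 54 of 56 (median 1.98), and respiratory chain genes in 49 of 91 (median 1.11), with Cox5b at 97.7 against 8.88 FPKM and Ndufa4 at 158 against 15.1 FPKM. At 1 FPKM there were 56 histone genes in GBC and 8 in HBC, so the filter on measured members favoured GBC for them.

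Epithelial basal genes were higher in HBC. Of 18 measured horizontal basal cell markers, 17 were at least 2-fold lower in GBC (median -4.98). The basal keratins Krt14 (451 against 0.397 FPKM), Krt5 (334 against 0.493 FPKM) and Krt17 (286 against 0.478 FPKM) led the list. Hemidesmosomes anchor basal cells to the basal lamina. The list called hemidesmosome genes here covers hemidesmosome and basal lamina adhesion and also holds desmosome genes such as Dsp. Its members were lower in GBC in 15 of 16 (median -2.86). Lamb3 had 67.6 FPKM in HBC and 0.103 in GBC, and Col17a1 had 57.1 and 0.175 FPKM. The Notch pathway had a median of -1.08 (9 of 15 lower), with Hes1 at 50.1 against 0.451 FPKM and Notch2 at 23.1 against 0.210 FPKM. Its percentile of 0.37 was 2.90 with 1 conversion factor per gene and 15.7 at the 20 FPKM filter.

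Genes of other cell types and of acute cell stress were high in the same HBC library and accompany each of these groups. All 22 macrophage and monocyte markers were at least 4-fold higher in HBC than in GBC (median -7.11), with Cd74 at 1228 against 1.03 FPKM, H2-Ab1 at 880 against 0.378 FPKM and Ctss at 638 against 0.534 FPKM. Interferon and MHC class I genes were lower in GBC in 17 of 18 (median -3.88), with H2-D1 at 387 against 1.75 FPKM. Neutrophil markers (median -2.94) and lymphocyte markers (median -2.57) were lower in GBC, with S100a9 at 60.2 against 4.88 FPKM and Cd4 at 21.2 against 0.0773 FPKM. Immediate early and dissociation response genes were lower in GBC in 21 of 22 (median -4.72), with Fosb at 701 against 9.53 FPKM and Atf3 at 527 against 3.99 FPKM. Sustentacular markers had a median of -2.84, with Cbr2 at 881 against 21.2 FPKM and Cyp2f2 at 748 against 3.97 FPKM. Bowman gland markers (median -2.21), fibroblast and smooth muscle markers (median -2.00) and endothelial markers (median -1.38) were lower in GBC too, with Dcn at 62.1 against 0.446 FPKM. At 1 FPKM there were 15 lymphocyte markers in HBC and 0 in GBC, and 14 and 0 endothelial markers. The filter on measured members therefore favoured HBC in both lists. Limited to members of at least 20 FPKM, some medians were larger in size but lay inside the random range. They were those of hemidesmosome genes (-3.50), the Notch pathway (-2.38), fibroblast and smooth muscle markers (-2.69), neutrophil markers (-3.31), lymphocyte markers (-4.36) and ciliary genes (2.72). The random lists were then drawn from genes under the same filter. Lymphocyte markers lay at a percentile of 64.2, so fewer members alone do not explain the loss.

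By the fixed rule, 1410 genes were higher in GBC and 1503 in HBC, of 9101 reaching 5 FPKM in either. The largest ratios in favour of HBC were those of Apoe (5045 against 5.28 FPKM), H2-Ab1, Cd74, H2-Aa, Ctss, Krt14, H2-Eb1 and C1qb. The largest in favour of GBC were Tubb2a-ps2 (328 against 0.455 FPKM), Stmn2, Neurog1, Tubb3 (407 against 1.87 FPKM), Gap43, Gng8, Tubb2b and Dpysl5 (192 against 0.935 FPKM). Tubb2a-ps2 is a tubulin pseudogene with close copies and its value is uncertain. The median gene was higher in GBC by 0.51 on the log2 scale. The share of called genes higher in GBC was 48.4% as deposited, 50.2% rescaled to a common sum, 31.5% with median-of-ratios scaling and 47.4% with 1 conversion factor per gene. With 1 conversion factor per gene, 52 of the 133 genes in the rule for this comparison moved by over 1.5-fold and none with at least a 2-fold difference changed sign. Cbx3 moved most, from a log2 ratio of 2.79 to 0.92, and Apoe went from -9.65 to -8.22, behind Ctss, H2-Aa, Cd74, H2-Ab1 and H2-Eb1. Medians inside the random range were 0.32 for DNA methylation genes, 0.35 for housekeeping genes, 0.42 for ribosomal protein genes, 0.82 for the cell cycle and 0.92 for Polycomb and heterochromatin regulators. They were 1.05 for trace amine receptors, 1.28 for erythroid markers, -0.46 for microvillous and tuft cell markers and -1.90 for ensheathing glia markers. Olfactory receptor genes had a median of 1.32, with 398 of 437 measured at least 2-fold higher in GBC. Of these genes, 436 reached 1 FPKM in GBC and 1 in HBC, so the filter on measured members favoured that direction. The list of the 3 sort genes had a median of 2.56, which was that of Omp, with Icam1 at -7.04 and Neurog1 at 7.28. Its percentile of 98.5 was 91.2 at the 20 FPKM filter and 96.9 rescaled to a common sum. No vomeronasal receptor gene was measured.

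The mOSN and HBC libraries stand at the ends of the lineage. Mature neuron markers were at least 4-fold higher in mOSN in 22 of 22 (median log2 ratio 5.45) and signal transduction genes were at least 2-fold higher in 17 of 21 (median 4.81). Gnal, the olfactory G protein subunit, had 1141 FPKM in mOSN and 9.87 in HBC, and Cnga2, a subunit of the olfactory transduction channel, had 570 and 6.44 FPKM. The receptor transport genes Rtp1 (428 against 3.16 FPKM) and Rtp2 (299 against 2.05 FPKM) and the peptide gene Cartpt (367 against 1.45 FPKM) were among the 8 largest ratios, with S100a5, Gnal, Nsg1, Gng13 and Ctxn3. Synaptic vesicle genes had a median of 3.91 (21 of 21 higher), with Snap25 at 161 against 2.504 FPKM. Axon guidance genes had a median of 3.36 and ciliary genes 3.05, with Cntn4 at 271 against 2.44 FPKM and Ift80 at 64.3 against 2.75 FPKM. Motile multiciliated cell markers (median 3.59), immature neuron markers (3.05), trace amine receptors (2.82), olfactory receptors (2.39), lineage transcription factors (1.83), histone genes (1.43) and respiratory chain genes (1.43) were also higher as groups. Of 1112 olfactory receptor genes, 930 reached 1 FPKM in mOSN and 1 in HBC. Of trace amine receptors 12 and 0 did, and of histone genes 32 and 8. The filter on measured members therefore favoured mOSN in these lists.

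The macrophage list was at least 4-fold lower in mOSN in 22 of 22 (median -7.31) and horizontal basal cell markers were lower in 17 of 18 (median -5.12). Interferon and MHC class I genes (median -3.94), hemidesmosome genes (-3.92), immediate early genes (-3.72), neutrophil markers (-3.20), lymphocyte markers (-2.91) and sustentacular markers (-2.37) were lower in mOSN. So were Bowman gland (-2.26), fibroblast and smooth muscle (-2.21) and endothelial markers (-1.69), the Notch pathway (-1.63) and ribosomal protein genes (-0.51). No lymphocyte or endothelial marker reached 1 FPKM in mOSN, so the filter on measured members favoured HBC in these lists. Hspa1a, an inducible heat shock gene, had 238 FPKM in HBC and 1.94 in mOSN, and the cytokine gene Il1b had 403 and 0.405 FPKM. Lists inside the random range were ensheathing glia markers (-1.37), the cell cycle (-0.66), precursor markers (-0.20), housekeeping genes (0.03), DNA methylation genes (0.09), erythroid markers (0.09), Polycomb and heterochromatin regulators (0.70) and microvillous and tuft cell markers (1.20). The sort marker and vomeronasal receptor lists had too few measured members. Limited to members of at least 20 FPKM, the Notch pathway (-4.12), fibroblast and smooth muscle (-3.45), lymphocyte (-4.47) and neutrophil markers (-3.92) lay inside the random range. By the fixed rule, 2351 genes were higher in mOSN and 1549 in HBC. The share of called genes higher in mOSN was 60.3% as deposited, 49.3% rescaled to a common sum, 40.9% with median-of-ratios scaling and 49.1% with 1 conversion factor per gene, and the median gene was higher in mOSN by 0.79. With that factor, 46 of the 135 genes in the rule for this comparison moved by over 1.5-fold, Bmi1 most, from a log2 ratio of 2.67 to 1.29.

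A gene was also assigned to 1 library where it exceeded both other libraries at least 4-fold, and most genes were assigned to none. Of 10340 genes reaching 5 FPKM, 1298 were highest in HBC, 144 in GBC and 503 in mOSN. The 1298 included all 22 macrophage markers, 16 immediate early genes, 14 horizontal basal cell markers and 13 hemidesmosome genes. The 144 included 11 immature neuron markers, 8 precursor markers and 6 histone genes. The 503 included 199 olfactory receptor genes, 12 mature neuron markers, 12 signal transduction genes and 6 trace amine receptors. Of the 503, 79 genes were higher at each step from HBC to GBC to mOSN, among them S100a5, Gnal, Cnga2 and Gng13. Of the 1298, 7 were lower at each step.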

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

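The alternatives with 1 conversion factor per gene and without FAIL and LOWDATA rows were chosen after seeing the data. No list median outside the random range reversed its sign, and no named gene with at least a 2-fold difference did, under any alternative run on it. Smaller values did: 11 list medians inside the random range, among them housekeeping and DNA methylation genes against HBC, and 9 log2 ratios of named genes had the other sign under at least 1 alternative. Of the list medians outside the random range, 12 of 17 (mOSN against GBC), 15 of 25 (GBC against HBC) and 19 of 25 (mOSN against HBC) stayed outside under all 8 alternatives. The 20 FPKM filter left too few members for a value in 3, 3 and 2 others, which stayed outside under the rest. Most of the remaining lists came inside at that filter, with medians at least as large. Their random lists were drawn from genes under the same filter, so those percentiles rest on a different pool of genes. The gene counts stayed within 1.5-fold with a pseudocount of 0.1 FPKM, without a filter, with the highest row per symbol, with separate intervals, without predicted genes and without FAIL and LOWDATA rows. In the order higher in mOSN than GBC, GBC than mOSN, GBC than HBC, HBC than GBC, mOSN than HBC, HBC than mOSN, and highest in HBC, GBC and mOSN, a pseudocount of 5 FPKM gave 173, 88, 504, 643, 918, 645, 564, 58 and 144 genes, and the filter at 20 FPKM gave 305, 109, 663, 638, 1143, 632, 560, 74 and 253, both by their construction. Rescaling to a common sum (TPM scale) multiplied HBC by 5.89, GBC by 5.44 and mOSN by 4.19, which lowers the level at which the pseudocount and the filter act. It gave 957 genes higher in GBC than mOSN, 2771 in GBC than HBC, 2753 in HBC than GBC and 3146 in HBC than mOSN, with 2454 highest in HBC and 428 in GBC. Median-of-ratios scaling gave 1484 genes higher in mOSN than HBC and 331 highest in mOSN. With 1 conversion factor per gene 449 genes were higher in GBC than mOSN, 262 of them shared with the 274, and 240 were highest in GBC, where the cause was not tested. Receptor genes in HBC, GBC and mOSN numbered 232, 1052 and 1065 at 0.1 FPKM, 0, 21 and 414 at 5 FPKM, and 153, 1018 and 1043 at 1 TPM, so the gap between GBC and mOSN depended on the threshold. Depth limits low genes, and 1 library per group leaves biological spread unmeasured. No paired analysis was possible because each group had 1 library and no result came from a test.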

Other observations

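Of the tests in this part, those on leukocytes, on ensheathing glia, on a fixed share of mature neurons and on the conversion from fragments to FPKM were chosen only after the result was seen. The test on transcript length was written before its result was seen.

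The genes named in this paragraph and the next were chosen after their values were seen. By the fixed rule, 45 genes were lower in GBC than in both HBC and mOSN. The 6 of them with the highest FPKM in mOSN were Nfe2l2, Tmem64, Fosb, Lgmn, Bcl6 and Il6st. Nfe2l2, a transcription factor of the antioxidant response, had 64.6 FPKM in HBC, 14.8 in GBC and 97.0 in mOSN, and Tmem64 had 20.5, 3.91 and 67.7 FPKM. The immediate early gene Fosb had 701, 9.53 and 67.5 FPKM, and the lysosomal protease gene Lgmn had 119.9, 11.3 and 54.9 FPKM. Bcl6, a transcriptional repressor, had 18.8, 2.60 and 41.6 FPKM, and the cytokine receptor subunit Il6st had 63.4, 3.63 and 32.3 FPKM.

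Of the 7 genes lower at each step, Tmem176b had 343 FPKM in HBC, 17.4 in GBC and 2.02 in mOSN, and Ezr, which links the membrane to actin, had 70.6, 14.4 and 2.52 FPKM. Among receptor genes, 18 were at least 2-fold higher in GBC than in mOSN. Olfr24 (chromosome 9, 18559136 to 18560077, mm9) had 5.97 FPKM in GBC and 2.26 in mOSN, and Olfr1535 (chromosome 13, 21646909 to 21647889) had 3.06 in GBC and was listed at 0 in mOSN. On the 4 chromosomes with the most receptor genes, the share reaching 1 FPKM in GBC was 31.3% of 284 (chromosome 2), 39.4% of 236 (chromosome 7), 27.5% of 138 (chromosome 9) and 59.3% of 81 (chromosome 11). In mOSN it was 84.5%, 86.0%, 75.4% and 75.3%. The mitochondrial leucyl-tRNA synthetase gene Lars2 had 1016 FPKM in HBC, 47.5 in GBC and 17.6 in mOSN.

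Macrophage and MHC class II transcripts were high in the HBC library. Of the 19 macrophage markers outside MHC class II, none of which stands in another list, 100% reached 20 FPKM in HBC and 17 were under 1 FPKM in both other libraries, which restates the pattern and decides nothing about its source. Ensheathing glia, which express Apoe, are a poor candidate source of its 5045 FPKM, since the median of their 13 markers in HBC was 0.01109% of it, with Fabp7 at 3.48 FPKM. Leukocytes are known to carry CD54, the antigen of this sort, and the labels name no gate that would remove them, but leukocytes in the sort and expression in the basal cells themselves cannot be told apart here. Both stay open as hypotheses, and kit and population are confounded.

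Receptor and transduction transcripts were present in the GBC library, and a fixed share of mature neurons in the Neurog1-EGFP sort would put a floor under the ratio of GBC to mOSN for every gene of mature neurons. The summed receptor FPKM in GBC was 22.0% of that in mOSN, yet 9.629% of the 2669 genes of at least 20 FPKM in mOSN lay below that ratio, among them Slc1a2 at 2.71%, Adcy3 at 6.002% and Gng13 at 20.9%. The 22 mature neuron markers had a median ratio of 21.7%, close to that of the receptors, with Omp at 28.7% and Rtp2 at 32.5%. With 1 conversion factor per gene the receptor ratio was 18.1% and the share below it 5.446% of 2075 genes. That is close to the limit of 5%, which was set after the result was seen. The count also took genes to which the floor need not apply, such as the sustentacular marker Ugt2a1 (3.63 FPKM in GBC, 31.4 in mOSN). By mature neuron markers such as Adcy3 and S100a5 (6.349%), a fixed share of mature neurons does not account for the whole receptor signal. A smaller share of mature neurons may account for part of it. Receptor transcription in other cells of that sort stays open as an untested hypothesis. In GBC the median was 109 FPKM over immature neuron markers and 17.6 FPKM over globose basal cell and precursor markers.

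Respiratory chain transcripts were lower in the HBC library than in both others. With 1 conversion factor per gene the median of GBC over HBC was 1.02, at the 99.95th percentile of random lists, so the authors' conversion from fragments to FPKM does not account for the difference. Matched also on the implied effective length, the median lay at the 99.8th percentile, past the limit set in advance for excluding a loss of short transcripts in the ScriptSeq library. That limit was wrong, because the implied length is not a transcript length: in GBC it was 0.9515 of the locus length for short receptor loci and 3.298 times it for short histone loci. Loss of short transcripts and a difference between the populations cannot be told apart, since the HBC population has 1 library and its own kit.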
